A study of Homo sapiens with 30 samples.

How the data were processed

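Total RNA from human left ventricle was measured on Affymetrix GeneChip Human Exon 1.0 ST arrays, per the labels' protocols, with 1 array for each of 30 samples. The labels place 15 samples in a control group with normal ventricular function and 15 in an ischemic heart failure group. RNA was labelled by random priming, per the labels' protocols. The expression values were deposited by the authors on the log2 scale, after RMA in Affymetrix Power Tools 1.0.12, per the submitters' processing notes. RMA corrects the background of each probe, brings arrays to a common distribution and condenses the probes of a feature to 1 value. The variant of RMA, the probe selection and the genome build are not given in the sources used here, so no coordinates are printed. That the scale is log2 and that each feature stands for a gene was read from the values and the feature identifiers.

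The deposited table held 22011 features with values from -0.92 to 11.71. The platform annotation gave 1 gene for 14432 features, several genes for 2408 and no gene name for 5171. Of the features with 1 gene, 14404 had a gene identifier in the RefSeq table of assembly GRCh38.p14, which was used for names alone, and 28 had none and kept the platform's symbol. No gene was named from a feature with several genes. Y-linked genes, XIST and TSIX were left out of all tests, which removed 9 features with 1 gene and, where all features were tested, 24 features with several genes that hold such a gene, leaving 21978. Where a gene had more than 1 feature (197 genes), the feature with the highest mean over all samples was kept. This left 14223 genes, and dim features were kept.

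Control and heart failure samples were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the values as deposited, without a block or covariate. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05, and a fold of at least 1.5 was counted separately. Each numbered sample was treated as a separate heart, so p-values measure the spread between these samples. The number of arrays limits the precision, and signal over background per feature was not used here. No scan date or batch is given in the sources used here.

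The members of 39 gene lists of cardiac pathways and cell types were tested with camera at a preset correlation of 0.01, two-sided, adjusted over the lists. Members past the threshold were counted with adjustment over all genes and adjusted over the list alone. The named genes were set by a rule. It took the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with at least 12 of 15 heart failure samples on the same side of the control median. From each list it took up to 4 members past the threshold with the largest change, or, where none passed, up to 2 with the smallest p. NPPA, NPPB, MYH6, MYH7, TNNT2, TNNI3, FLNC and ATP2A2 were always included. Genes outside the rule are marked where they appear. The grouping, limma and camera tests, lists, naming rule and other settings, apart from those named as added, were fixed before the data were examined. The explanations weighed in the later sections concern patterns seen in the results. Their limits were written after these patterns were seen and before each explanation was tested.

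The other settings were quantile normalization, median centring, filters on dim features, an intensity trend with a robust prior, array weights, a Wilcoxon rank-sum test, a replicate block, the first residual principal component as a covariate, the mean of a gene's features, all features, a threshold of 0.01, leaving out each sample in turn, camera with an estimated correlation, fry, and members of 1 list only. Added after seeing the data were each array's interquartile range as a covariate, 2 sets of left-out samples, and a two-sided permutation test of list means with 100000 resamples. Intervals of score differences came from 10000 bootstrap draws. These used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

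The fit was tested on simulated data for heart failure against control, with 14223 genes of which 200 were changed. It recovered 81% of the 100 genes changed 1.5-fold and 100% of the 100 changed 2-fold, and called 14 unchanged genes. Camera called 1 list when the macrophage list alone was lowered. Each simulated gene was drawn independently, so these values do not show how often camera or the fit errs with correlated genes.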

Results

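Gene expression was compared between left ventricular tissue of 15 hearts with ischemic heart failure, taken away from the infarct, and 15 control hearts. Each array gave 1 log2 value per gene, and 14223 genes were tested. Array medians lay between 3.65 and 3.95. The mean array median was 3.84 ± 0.06 (SD, n = 15) in control samples and 3.78 ± 0.08 in heart failure samples (two-sided permutation test, p = 0.0311). The interquartile range of the arrays was 3.24 ± 0.11 in control and 3.14 ± 0.16 in heart failure samples (p = 0.0540). The first principal component of the genes held 24.2% of the variance and followed this range across arrays (r = -0.935). Control samples 8, 12 and 14 lay at 42.1, 47.0 and 40.7 on the second component, which held 18.2%, while the other samples lay between -22.1 and 17.6.

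The first comparison asked which genes differ between failing and control ventricle. Heart failure samples had more transcript of the natriuretic peptide gene NPPA and of several secreted matrix genes, and less of SERPINA3, FCN3 and genes of tissue macrophages. NPPA, which encodes atrial natriuretic peptide (transcript cluster 2396848), rose from 5.23 ± 1.63 (SD, n = 15) to 8.38 ± 1.17, a log2 difference of 3.15 (SE 0.49) or 8.88-fold (limma, adjusted p = 5.69e-04). All 15 heart failure samples lay above the control median, and 2 control samples lay above the lowest heart failure sample. SFRP4, a secreted frizzled-related protein (3046444), rose 4.56-fold, from 2.73 ± 0.79 to 4.91 ± 1.28 (adjusted p = 9.24e-04). SERPINA3, an acute-phase protease inhibitor (3549757), fell by 2.44 on the log2 scale (SE 0.32), from 6.44 ± 1.01 to 3.99 ± 0.85 (adjusted p = 9.75e-05), and all 15 heart failure samples lay below the control median.

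FCN3, a lectin of the complement system (2403080), had the smallest adjusted p among the named genes. It fell by 1.52 on the log2 scale (SE 0.13), from 4.92 ± 0.49 to 3.40 ± 0.19 (adjusted p = 7.33e-09). The highest heart failure sample measured 3.80 and the lowest control sample 3.75. The next largest rises were in ASPN, LUM, NAP1L3, OGN, OMD, COL14A1, FMOD and PRELP, with log2 differences from 1.63 in ASPN to 1.07 in PRELP. The next largest falls were in PLA2G2A, CD14, LYVE1, FCER1G, IFI30, VSIG4, TMT1B and ETNPPL, with log2 differences from -1.52 in PLA2G2A to -1.26 in ETNPPL. The naming rule required at least 12 of the 15 heart failure samples on the side of the change, so this holds for each of these genes by selection. NPPB, the gene of brain natriuretic peptide, measured 9.22 ± 0.95 in heart failure and 7.35 ± 2.22 in control samples, a log2 difference of 1.87 (SE 0.59) that did not pass (adjusted p = 0.0545), with 15 of 15 heart failure samples above the control median.

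**Figure D1:**
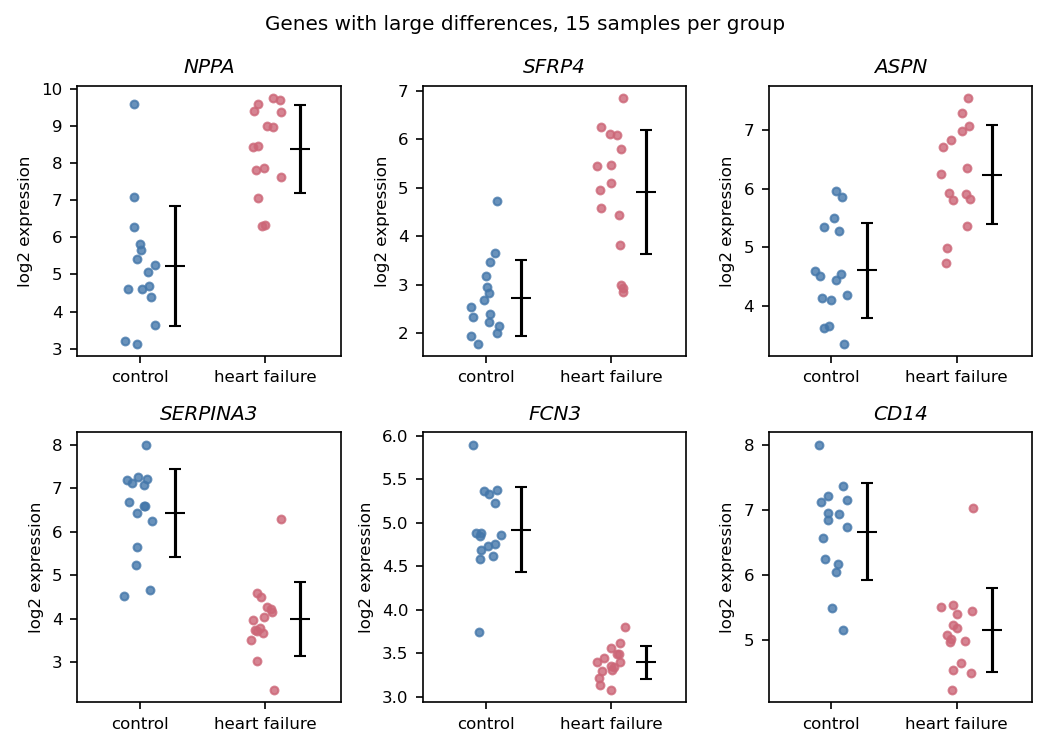
Log2 expression (vertical axes) of NPPA, SFRP4, ASPN, SERPINA3, FCN3 and CD14 in 15 control and 15 heart failure samples; points are samples, and bars are the mean ± SD. NPPA, SFRP4 and ASPN were higher in heart failure and the other genes lower, and the groups overlapped least in FCN3, where the highest heart failure sample was 3.80 and the lowest control sample 3.75.

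In all, 834 of 14223 genes passed an adjusted p of 0.05 with limma, 104 higher and 730 lower in heart failure. Without heart failure sample 2, 1338 genes passed, 1197 of them lower. Most differences were small, with a median absolute log2 difference of 0.385, and 692 of these genes changed less than 1.5-fold. A fold of at least 1.5 was reached by 142 genes, 45 higher and 97 lower (148 lower without heart failure sample 2). The balance of directions depended on the scaling of the arrays. Lower genes made up 87.5% with the deposited values, 64.4% after median centring (184 higher, 333 lower) and 50.1% after quantile normalization (206 higher, 207 lower). Of the 54 genes past the threshold that the naming rule took, all kept their direction under both scalings, and 18 lost their call after quantile normalization: CAPZB, ANKRD2, ENO1, HCN4, KCNH2, PPP1R1A, PDE4D, ADRA1B, GRK2, ATP5MC1, TGFBR3, S100A9, OSMR, STAT3, HSPB7, RPS23, MCM5 and ENG. Without control samples 8, 12 and 14, 16 of the 54 lost their call: FMOD, ANKRD2, ENO1, PDE4D, ADRA1B, TIMP2, HTRA1, LTBP3, FRZB, WNT9A, S100A9, XAF1, HSPB7, RPS23, MCM5 and FPR1.

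**Figure D2:**
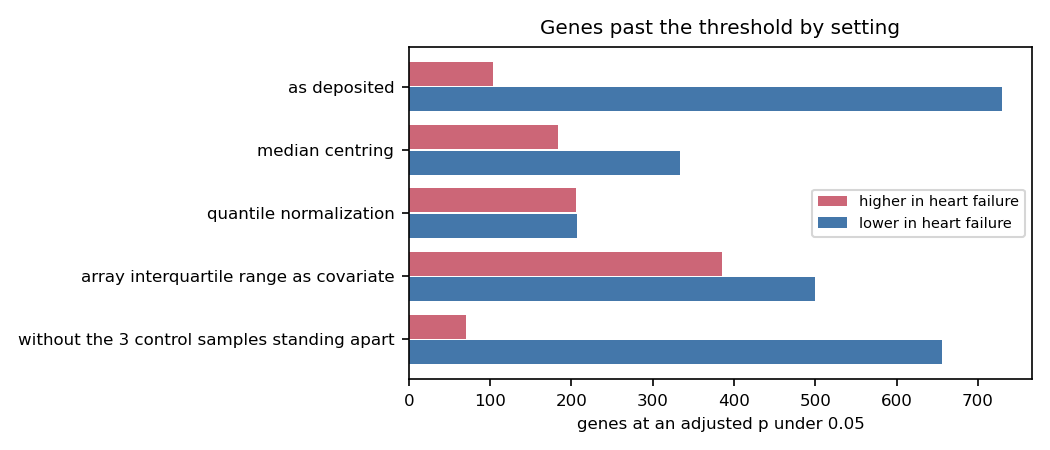
Number of genes past an adjusted p of 0.05 (horizontal axis), higher or lower in heart failure, with the values as deposited and under 4 other settings. The deposited values gave 104 higher and 730 lower genes, and quantile normalization gave 206 and 207.

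The title of the series concerns sarcomere genes and their splicing. At the level of whole genes, 2 of 51 measured sarcomere and Z-disc genes passed, against 834 of all 14223 genes tested. The count alone does not set these genes apart. None rose and 2 fell, with a median log2 difference of -0.008 and 48 genes under 1.5-fold. The wide intervals of some genes leave larger differences open, and 6 genes passed with array weights and 6 with the first residual principal component as a covariate. CAPZB, which caps the ends of actin filaments, fell by 0.31 (SE 0.07, adjusted p = 0.0133, 14 of 15 samples below the control median). ANKRD2, a stretch-responsive ankyrin repeat protein, fell by 0.90 (SE 0.28, adjusted p = 0.0491, 11 of 15 samples). TNNI3, cardiac troponin I, measured 10.72 ± 0.28 in heart failure and 10.63 ± 0.17 in control samples (adjusted p = 0.597).

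Of the thick filament list, 0 of 15 measured genes passed, also when adjusted over the list alone, and camera gave an adjusted p of 0.265. In the thin filament list, CAPZB passed among 13 genes (1 up and 1 down adjusted over the list alone, camera adjusted p = 0.283). In the Z-disc and costamere list, ANKRD2 passed among 23 genes (0 adjusted over the list alone, camera adjusted p = 0.560). Over all genes, 2946 passed an unadjusted p of 0.05 and the Wilcoxon test called 770 genes. The call of CAPZB was lost after quantile normalization, and that of ANKRD2 stood in 6 of the 30 fits that left out 1 sample. MYH6, MYH7, TNNT2, FLNC and MYBPC3 are not analysed here, and neither is exon usage, which values per gene do not resolve.

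**Figure D3:**
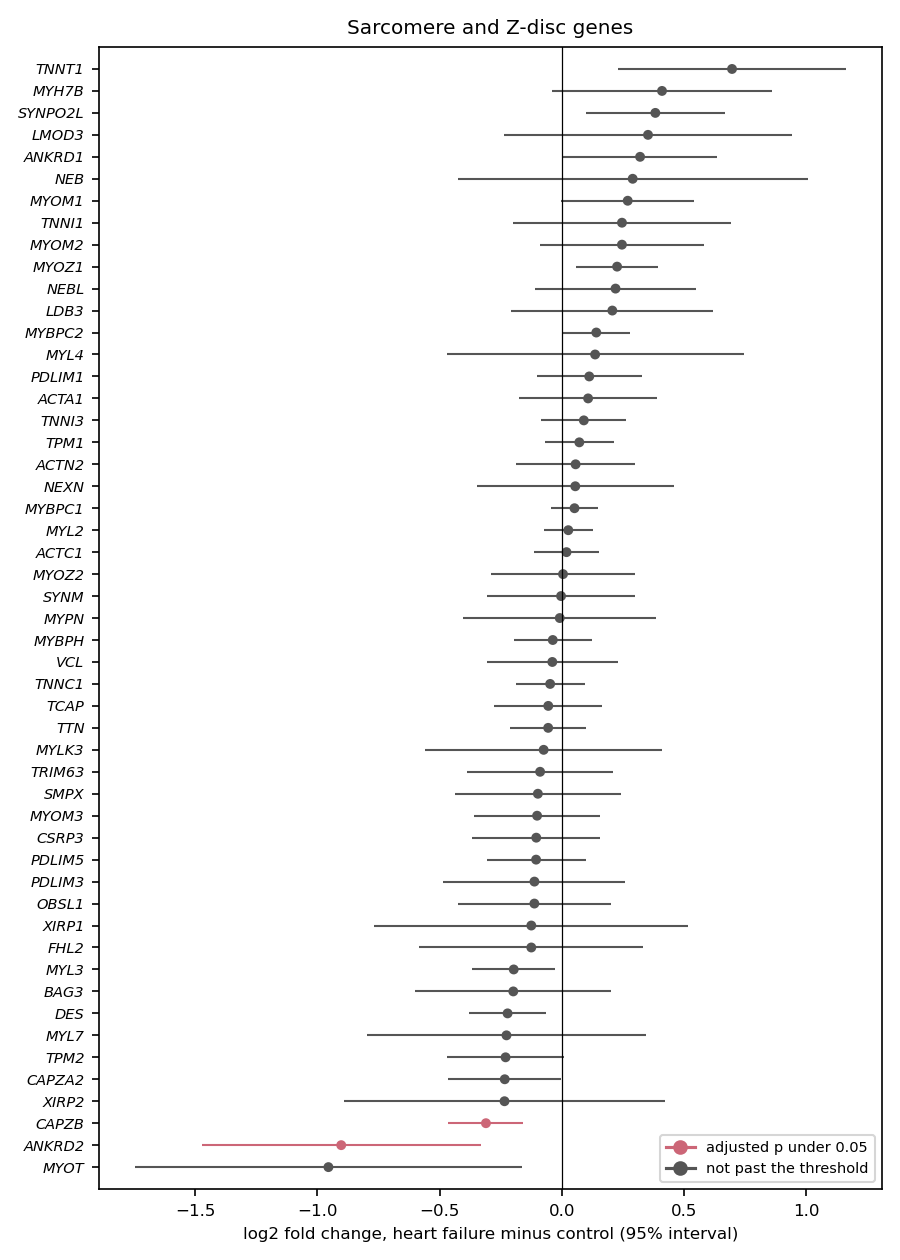
Log2 fold change of 51 sarcomere and Z-disc genes, heart failure minus control (horizontal axis), with 95% intervals as lines. CAPZB at -0.31 and ANKRD2 at -0.90 passed an adjusted p of 0.05, and the other genes, from MYOT at -0.95 to TNNT1 at 0.70 (named after their values were seen), did not.

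The next comparison asked which of 39 fixed gene lists shifted. Of 41 extracellular matrix genes, 14 rose, none fell and 27 did not pass (15 rose and 0 fell adjusted over the list alone). The list median was 0.45, and 11 of 15 heart failure samples had a list mean above the control median. ASPN rose 3.10-fold, LUM 2.61-fold, OGN 2.34-fold and OMD 2.33-fold, and these 4 genes encode small leucine-rich proteoglycans that bind collagen. Camera gave the matrix list an adjusted p of 1.61e-19. With an estimated correlation the adjusted p = 0.269. The fibroblast marker list rose as well (median 0.38, camera adjusted p = 3.67e-05, adjusted p = 0.279 with an estimated correlation), with LUM past the threshold among 16 genes (3 adjusted over the list alone), and its camera call was lost when members shared with another list were left out. The list mean of the fibroblast markers was 6.13 ± 0.24 in control and 6.50 ± 0.40 in heart failure samples. Heart failure sample 5 had the highest matrix score (7.11) and fibroblast score (7.32) and the lowest cardiomyocyte score (9.08) of all samples, and without it the list medians were 0.35 for matrix genes and 0.31 for fibroblast markers.

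Wnt pathway genes and secreted Wnt antagonists also rose, 4 of 20 up and none down (the same counts adjusted over the list alone). SFRP4, FRZB (0.78), WNT9A (0.60) and LEF1 (0.40) were the 4, and SFRP4 and FRZB encode secreted proteins that bind Wnt ligands. Both group means of LEF1 lay under the lower quartile of every array (1.99 to 2.10), so it is not shown to be above background. Camera gave an adjusted p of 5.93e-05. With an estimated correlation the adjusted p = 0.161. FRZB passed in 9 of the 30 fits that left out 1 sample, and WNT9A in 23. In the natriuretic and fetal program, NPPA rose, and ENO1 (-0.52) and HCN4 (-0.38) fell, among 14 genes (3 up and 4 down adjusted over the list alone, camera adjusted p = 0.267).

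Macrophage and monocyte markers fell: 10 of 16 were lower and none higher (13 adjusted over the list alone), with a list median of -0.69. CD14, a co-receptor for bacterial lipopolysaccharide, fell by 1.51 (SE 0.24). LYVE1, a hyaluronan receptor of resident macrophages and lymphatic vessels, fell by 1.47 (SE 0.29), VSIG4, a complement receptor, by 1.28 (SE 0.25) and the haemoglobin scavenger receptor CD163 by 1.19 (SE 0.27), each in 14 of 15 samples. Camera gave an adjusted p of 3.39e-09. With an estimated correlation the adjusted p = 0.508, and fry, which tests the direction of the list alone, gave 0.0339. The same heart failure sample 5 had a macrophage score of 6.29, against a heart failure mean of 4.68 ± 0.55 and a control mean of 5.45 ± 0.51, and without it the list median was -0.80.

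Acute-phase and alarmin genes fell, 4 of 21 lower and none higher (6 adjusted over the list alone, median -0.40). Beside SERPINA3 these were S100A9 (-0.87), a neutrophil and monocyte alarmin, the oncostatin M receptor OSMR (-0.83) and the transcription factor STAT3 (-0.57). Camera gave an adjusted p of 0.00305. With an estimated correlation the adjusted p = 0.726. Neutrophil markers fell, with S100A9 and the formyl peptide receptor FPR1 (-0.82) lower among 11 genes (5 adjusted over the list alone, camera adjusted p = 0.0209). With an estimated correlation the adjusted p = 0.922, and by a permutation of list means 0.0775. Without control samples 8, 12 and 14 neither list passed, and the calls of S100A9 and FPR1 were lost.

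The interferon response list rose by camera (median 0.30, adjusted p = 1.31e-05, adjusted p = 0.667 with an estimated correlation), with XAF1 (0.33) past the threshold among 19 genes (4 adjusted over the list alone). Its list mean lay above the control median in 8 of 15 heart failure samples and did not pass a permutation test of list means added after seeing the data (adjusted p = 0.265). Lymphocyte markers had a median of 0.15 and rose by camera (adjusted p = 0.00284, adjusted p = 0.726 with an estimated correlation), although none of 16 members passed, also adjusted over the list alone, and the camera call was lost when the dimmest genes were left out and in the permutation test (adjusted p = 0.510). Red cell markers rose by camera (median 0.05, adjusted p = 0.0415, adjusted p = 0.667 with an estimated correlation), with the beta-globin gene HBB (1.04, SE 0.27) past the threshold among 8 genes (2 up and 1 down adjusted over the list alone). The red cell call was lost after quantile normalization, after median centring, without control samples 8, 12 and 14 and in the permutation test (adjusted p = 0.128). Its median was -0.03 with the array interquartile range as a covariate.

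**Figure D4:**
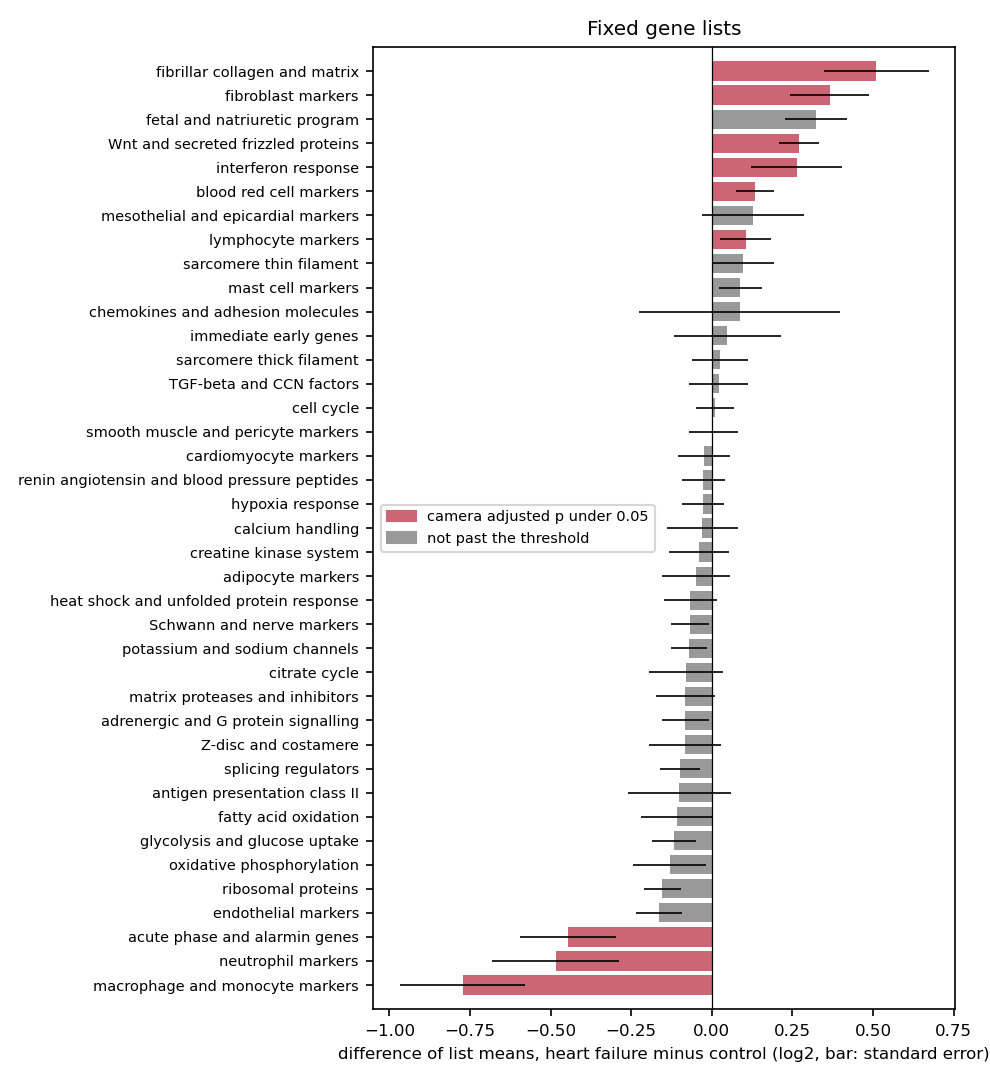
Difference of list means, heart failure minus control in log2 units (horizontal axis), for 39 fixed gene lists, with bars of 1 standard error; red bars passed camera at an adjusted p of 0.05. The macrophage list lay lowest at -0.77 and the matrix list highest at 0.51.

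Camera placed 9 lists past the threshold, 6 up and 3 down, and none of these calls held with an estimated correlation. Other splits of the 30 samples gave as many lists in 69 of 100 draws, the real split included. The other 30 lists did not pass. For 10 lists the median, the mean and the camera direction differed in sign, and none of them passed: thick filament, Z-disc and costamere, calcium handling, potassium and sodium channels, matrix proteases, class II antigen presentation, hypoxia response, renin-angiotensin, cardiomyocyte markers and adipocyte markers.

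Ion channel genes moved both ways. SCN2B, a sodium channel beta subunit, rose by 0.86 (SE 0.16, adjusted p = 0.00259) and the calcium-activated potassium channel KCNN3 by 0.39 (SE 0.08). KCND3, a subunit of the transient outward potassium current, fell by 0.61 (SE 0.11, adjusted p = 0.00224) and KCNH2, of the rapid delayed rectifier, fell by 0.40 (SE 0.09). In all 2 of 24 channel genes rose and 3 fell (3 and 5 adjusted over the list alone, camera adjusted p = 0.772). Camera asks for a shift in 1 direction. The mixed form of fry, which asks for changes in either direction, gave an adjusted p of 1.29e-08. It does not weigh the list against the other genes. The calcium pump gene ATP2A2 measured 9.39 ± 0.26 in heart failure and 9.67 ± 0.31 in control samples (adjusted p = 0.102), and 0 of 18 calcium handling genes passed, also adjusted over the list alone (camera adjusted p = 0.653). PPP1R1A (-0.62), PDE4D (-0.47), ADRA1B (-0.33) and GRK2 (-0.25) fell among 20 adrenergic and G protein genes, 4 also adjusted over the list alone (camera adjusted p = 0.653). These 4 calls were lost after quantile normalization. Of the 30 fits that left out 1 sample, PPP1R1A passed in 14, PDE4D in 13, ADRA1B in 20 and GRK2 in 30.

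Markers of other cell types differed less. The cardiomyocyte marker score was 9.83 ± 0.21 in control and 9.80 ± 0.24 in heart failure samples, with 0 of 14 genes past the threshold. Among 14 endothelial markers, ENG, a co-receptor for transforming growth factor beta, fell by 0.42 (SE 0.10, adjusted p = 0.0102), and the list did not pass camera (adjusted p = 0.163). No smooth muscle and pericyte marker passed among 12 (camera adjusted p = 0.364). In the list of transforming growth factor beta genes, TGFBR3 (-0.52) and TGFBR2 (-0.41) fell and LTBP3 (0.42) rose among 19 (camera adjusted p = 0.471). Among 24 matrix proteases and inhibitors, ADAMTS15 fell by 0.98 (SE 0.16, adjusted p = 8.62e-04), and TIMP2 (0.45) and HTRA1 (0.33) rose.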

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

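The tests with the array interquartile range as a covariate and without control samples 8, 12 and 14 used alternatives chosen after seeing the data.

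Features outside the named genes also carried differences. Among 5171 features with no gene named, 10 were higher and 92 lower in heart failure at an adjusted p of 0.05, and among 2384 features with several genes, none of them Y-linked, XIST or TSIX, 9 were higher and 87 lower. They were singled out because they lie outside the main measurement.

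More genes were lower than higher in heart failure, 730 against 104. Lower genes made up 56.4% of the calls with the interquartile range of each array as a covariate, with 385 genes higher and 499 lower. That share met the limit written beforehand for array spread as a cause of the imbalance. At a fold of at least 1.5, 85 genes were higher and 52 lower with this covariate. The interquartile range is taken from the same expression values, and averaged 3.24 in control and 3.14 in heart failure samples. The covariate would therefore also take up a real shift that follows the range. Array spread may account for the imbalance but is not shown to, and 499 genes were still called lower. Lower genes made up 50.1% after quantile normalization, which decides nothing. Giving all arrays the same distribution evens the directions whether the excess is technical or real. A difference in total transcript pattern between failing and control hearts stays open, since the values carry no external standard.

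Macrophage markers were lower in heart failure. A larger share of cardiomyocytes would lower the markers of every other cell type alike. But the endothelial score, the nearest of 3, changed by -0.16. It fell by 0.610 less than the macrophage score (95% bootstrap interval 0.229 to 0.944). The list median was -0.73 with the array interquartile range as a covariate and -0.60 without control samples 8, 12 and 14, which argues against array spread or those samples as the whole cause. A lower number or changed state of macrophages in failing hearts may remain as a hypothesis. Differences between donor and explanted hearts in handling or in the state of the control donors were not tested and stay open.

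Matrix genes were higher in heart failure. The matrix score rose by 0.354 more than the 10 fibroblast markers outside the matrix list (95% bootstrap interval 0.0193 to 0.679). That narrowly met the limit written beforehand against a larger share of fibroblasts as the whole cause. The 10 markers themselves changed by 0.155 (-0.0546 to 0.361). How closely they follow the share of fibroblasts was not tested, so the gap does not decide the question. The list median was 0.45 with the array interquartile range as a covariate, against array spread. A larger share of fibroblasts, a change in matrix expression within them and a mixture of both stay open.

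Chance was weighed with 100 splits, the real one included. The real split gave 834 genes and the highest other 1, so 1 of 100 splits was as large. The same share, 1 of 100, held for the 142 genes with a fold of at least 1.5 (highest other 1). A random split is thus an unlikely source of these 2 counts. Random splits do not test a technical difference that lies along the groups. For the 2 sarcomere genes (highest other 0) the splits say nothing, since no other split called more than 1 gene of any kind. Chance cannot be excluded for the count of 9 gene lists, since 69 of 100 splits gave as many and the highest other gave 21. The splits bear on this count and not on each list. In the permutation test of list means, added after seeing the data, 5 of the 9 lists passed. These were Wnt (adjusted p = 0.0078), macrophage (0.0105), matrix (0.0304), fibroblast (0.0372) and acute phase (0.0372), which argues against chance for these 5 alone.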

How the results depend on the processing

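The array interquartile range covariate, the 2 sets of left-out samples and the permutation of list means were chosen after seeing the data. No named gene or list passed in the opposite direction under any alternative run. Of 54 named genes past the threshold, 18 lost their call after quantile normalization, 10 after median centring, 12 with the array interquartile range as a covariate and 16 without control samples 8, 12 and 14, where 3 lists lost and 6 gained a call. The cause was not tested where a count moved, except that a stricter threshold calls fewer genes by construction. Quantile normalization gave 413 genes, 206 higher and 207 lower, of which 302 were shared with the 834, and 69 genes at least 1.5-fold higher and 43 lower. Median centring gave 517 genes, 184 higher and 333 lower, 55 of them at least 1.5-fold lower. Array weights gave 1975 genes, 271 higher and 1704 lower, 155 at least 1.5-fold lower, and 6 sarcomere genes. The first residual principal component as a covariate gave 1737 genes, 262 higher and 1475 lower, and 6 sarcomere genes. The intensity trend with a robust prior gave 1 sarcomere gene. A threshold of 0.01 gave 205 genes, 27 higher and 178 lower, 56 with a fold of at least 1.5 (18 higher, 38 lower), and 0 sarcomere genes (2946 genes passed an unadjusted p of 0.05, and 834 limma at 0.05). The array interquartile range covariate gave 385 higher genes, 85 at least 1.5-fold higher and 52 lower. Without control samples 8, 12 and 14, 29 genes were at least 1.5-fold higher and 5 lists shifted down. Without heart failure samples 2 and 6, which lay at -50.3 and -33.4 on the first component, 1919 genes passed, 232 higher and 1687 lower. Of these, 221 had a fold of at least 1.5 (182 lower), and 4 were sarcomere genes. In that setting 1 list shifted down, as 2 lists lost a downward camera call and 1 list gained a call. That set of samples was picked by position, and control sample 1, at -39.7, was not left out with it. With an estimated correlation 0 lists shifted up and 0 down, and with fry 0 up and 1 down. The permutation of list means, run once these results were known, placed 6 lists past the threshold, 5 of them also past camera, and added the natriuretic and fetal program (adjusted p = 0.0299). The interferon (0.265), lymphocyte (0.510), neutrophil (0.0775) and red cell (0.128) lists lost their call there.

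Leaving out 1 sample gave 595 to 1338 genes, 77 to 147 higher and 507 to 1197 lower, 115 to 187 with a fold of at least 1.5 (35 to 61 higher, 72 to 148 lower), 1 to 3 sarcomere genes, 5 to 8 lists up and 2 to 4 down. The highest values, 1338, 1197 and 148, came without heart failure sample 2. Calls of named genes near the threshold were lost in some of these 30 fits, and ANKRD2, XAF1, FRZB, ATP5MC1 and TIMP2 passed in 6, 8, 9, 9 and 10 of them. The labels number the samples within each group, and the series text describes matched groups without naming pairs. The numbers were not shown to pair the samples: 4 of 15 same-number pairs correlated over 0.1 (median 0.00109), and 1 of 15 control samples correlated best with its own number, a hint from the data only. With the number as a replicate block 750 genes passed, 103 higher and 647 lower, of which 629 were shared with the 834, and 10 of the 54 named genes lost and 4 others gained a call, as 1 list lost its call. Signal over background was not used here, so the reliability of dim genes is not known.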

Other observations

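The genes compared in the next paragraph and the test without control samples 8, 12 and 14 were chosen after their values were seen, and so was the use of the 95% interval of r as its spread.

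Within the matrix list, more small leucine-rich proteoglycan genes than fibrillar collagen genes passed, and the ranges of both sets overlapped. Of 8 proteoglycan genes, 6 rose (ASPN, LUM, OGN, OMD, FMOD and PRELP), while DCN (0.29, adjusted p = 0.217) and BGN (0.45, adjusted p = 0.236) did not pass. Of 5 fibrillar collagen genes, 0 passed with limma, from COL5A2 at 0.25 to COL1A1 at 0.91 (adjusted p = 0.177), while 2946 of all genes passed an unadjusted p of 0.05 and the Wilcoxon test called 770 genes. The mean of the proteoglycan genes changed by 1.05 (95% bootstrap interval 0.680 to 1.41) and that of the collagen genes by 0.535 (0.00980 to 1.10), a difference of 0.512 (0.0298 to 1.01). These genes were picked because they showed the contrast, so the interval is a description and no test of it.

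Genes of energy metabolism did not pass as lists, with adjusted p by camera of 0.267 for oxidative phosphorylation, 0.460 for fatty acid oxidation and 0.772 for the citrate cycle. Without control samples 8, 12 and 14 the oxidative phosphorylation list passed camera with a median of -0.24 (adjusted p = 1.23e-04), as did fatty acid oxidation at -0.28 (adjusted p = 9.30e-04), the citrate cycle at -0.23 (adjusted p = 0.00497) and glycolysis at -0.18 (adjusted p = 0.0355). Immediate early genes (0.16, adjusted p = 0.00153) and mesothelial markers (0.18, adjusted p = 0.0179) passed upward without them. These 3 samples had the lowest cardiomyocyte scores of the control samples (9.71, 9.38 and 9.33). Their immediate early gene scores (6.15, 6.05 and 5.79) did not set them apart, since control samples 5 and 13 lay at 6.17 and 5.83. Camera called many lists in other splits of the samples, so these values are given as a dependence on 3 samples.

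A shared axis across samples was one hypothesis for genes that moved together, tested by 6 correlations within groups. The macrophage score and SERPINA3 correlated in control samples (r = 0.784, permutation p = 4.40e-04, adjusted p = 0.00264, rho = 0.657, p = 0.00916, adjusted p = 0.0550, n = 15), and without the 2 farthest samples r = 0.709. In heart failure samples r = 0.293 (95% interval -0.258 to 0.700, permutation p = 0.238, adjusted p = 0.307, rho = 0.536, p = 0.0420, adjusted p = 0.126), and without the 2 farthest r = 0.262. The r under 0.3 written beforehand as evidence against a shared axis was met by less than the spread, so the axis may still be shared. For FCN3, r = 0.311 in control samples (permutation p = 0.256, adjusted p = 0.307, rho = 0.207, p = 0.460, adjusted p = 0.460; 0.306 without the 2 farthest) and r = -0.226 in heart failure samples (95% interval -0.662 to 0.324, permutation p = 0.404, adjusted p = 0.404, rho = -0.311, p = 0.258, adjusted p = 0.310; -0.335 without the 2 farthest). For FCN3 the mark against a shared axis was met as well, and the interval lies wholly under the r required beforehand for one. It reaches past 0.3 and FCN3 varied little in heart failure samples (SD 0.19), so the axis is neither shown nor excluded. The matrix score and NPPA had r = 0.387 in control samples (permutation p = 0.155, adjusted p = 0.307, rho = 0.411, p = 0.129, adjusted p = 0.193; 0.389 without the 2 farthest) and r = 0.453 in heart failure samples (95% interval -0.077 to 0.783, permutation p = 0.0890, adjusted p = 0.267, rho = 0.414, p = 0.126, adjusted p = 0.193; 0.545 without the 2 farthest), which leaves the question open.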
